A study of Arabidopsis thaliana with 9 samples.

How the data were processed

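The series measured gene expression with arrays in quiescent centre (QC) cells of the Arabidopsis thaliana root, the slowly dividing cells around which the root stem cells lie. All plants carried mutations in PLT1 and PLT2, which encode AP2-type transcription factors of the root meristem, and a complementing PLT2 fusion to the glucocorticoid receptor (PLT2-GR) under the PLT2 promoter. Dexamethasone lets such a fusion enter the nucleus. Per the labels' protocols, 5-day seedlings were moved to plates with 10 µM dexamethasone for 1 h or 4 h, or to plates with solvent for 1 h (mock). Root tips were then digested to protoplasts, and cells with WOX5 promoter-driven GFP were sorted. Each of the 3 groups had 3 arrays, called biological replicates in the labels, and the p-values measure the spread among these. No mock array was incubated for 4 h, and no array came from dexamethasone-treated plants without the construct.

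The deposited values are log2 expression per probe set, made by the authors with RMA per the submitters' processing notes, which also name limma 3.24.15. The array type, the probe set definition and the genome build are not given in the sources used here. The table had 21494 probe sets, of which 64 were controls. The other 21430 carried an Arabidopsis locus as their name, 1 per locus, and 21231 of these matched the TAIR10.1 gene table used for symbols. No coordinates were used. Probes shared between close paralogs cannot be recognised without the probe set definition, so values of members of gene families are uncertain to that extent. WOX5, the reporter gene used in sorting, was not among the loci analysed here. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.108.

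The values were used as deposited, with no further normalization and no filter on dim probe sets. One limma 3.58.1 model in R 4.3.3 was fitted to all 9 arrays (lmFit, then eBayes), with 6 residual and 4.47 prior degrees of freedom. The contrasts were tested two-sided: 1 h against mock, 4 h against mock and 4 h against 1 h. P-values were adjusted by the Benjamini-Hochberg method over 21430 loci, and a gene was called at an adjusted p under 0.05. All adjusted p-values given for genes come from this limma model. Errors after ± are standard errors from the model unless marked SD. The 2 comparisons with mock share the same mock arrays, so 50 simulations of unchanged groups against shared controls gave the overlap and correlation that arise with no effect.

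Fixed before the data were examined were the contrasts, 20 gene lists and the rule for the genes named. The rule took the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between groups for each comparison with mock, and 4 of each between the times. It added up to 3 members with the smallest p from each list that shifted or had a called member, and PLT1, PLT2 and WOX5. Members named outside this rule were chosen after their values were seen. Each list was tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), again with the correlation estimated for each list, and with fry. Another 5 lists were chosen after seeing the data and appear only in the closing section.

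The model was tested on simulated data made from the 21430 loci. For 1 h against mock it recovered 98.2% of planted rises of 1 log2 unit, 98.5% of falls of that size and 51.5% of rises of 0.5, and 4.87% of its calls were false. For 4 h against mock it recovered 97.3% of rises of 1 log2 unit and 46.5% of rises of 0.5, and 5.37% of its calls were false. The simulated errors were independent, with the same spread in all groups, as the model assumes. The real median SD over genes was 0.10 in mock and 0.145 at 4 h. These shares therefore check the procedure and do not measure the false calls in the real data. Alternatives tried were quantile normalization, centring on array medians, leaving out the probe sets below the 40th percentile of mean level, trend and robust eBayes, array weights, only the 2 groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each array in turn. Testing all probe sets separately was the same as the model above, since each locus had 1 probe set.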

Results

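Expression of 21430 loci was measured in cells sorted as QC cells before and after the release of PLT2-GR by dexamethasone, with 3 arrays each for mock, 1 h and 4 h. The share of QC cells among the sorted cells was not measured. In mock, AGL42 of the niche regulator list had a mean log2 level of 2.88, below the first quartile of the arrays (3.55 to 3.63). The niche regulator SCR had a level of 8.55 and the root cap marker RCPG one of 11.6. Arrays of a group correlated across genes at 0.9962 to 0.9972 in mock, 0.9949 to 0.9969 at 1 h and 0.9902 to 0.9935 at 4 h. The median SD over genes was 0.10 in mock, 0.10 at 1 h and 0.145 at 4 h. On replicate 1 at 4 h the poly-A control RNAs added to the samples had a mean log2 level of 8.80, against 6.16 to 6.66 on the other 8 arrays. This array also had the highest 5S rRNA signal (5.63, others 4.59 to 5.04) and the largest difference between 3' and 5' actin probe sets (1.37, others 1.08 to 1.25). Its difference between 3' and 5' GAPDH probe sets (0.04, others -0.08 to 0.15) and its 25S rRNA signal (12.8, others 12.5 to 13.0) lay within the range of the other arrays. On the first principal component, with 48.9% of the variance, 4 h replicates 1, 2 and 3 lay at 40.7, 27.3 and 4.25, and 1 h replicate 1 at 0.6. PLT2 (AT1G51190) had a mean log2 level of 8.58 ± 0.07 (SD, n = 3) in mock, and PLT1 (AT3G20840) one of 4.33. Which part of PLT2 its probe set covers is not given in the sources used here, so the fusion gene and the mutated gene are not told apart. Neither was called against mock at 1 h (log2 fold change 0.34 ± 0.16 for PLT2 and 0.005 ± 0.09 for PLT1) or at 4 h (-0.02 ± 0.16 and 0.09 ± 0.09). The 3 PLT2 values at 1 h (8.79 to 9.14) all lay above the 3 in mock (8.53 to 8.66), so a rise of PLT2 at 1 h is left open.

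**Figure D1:**
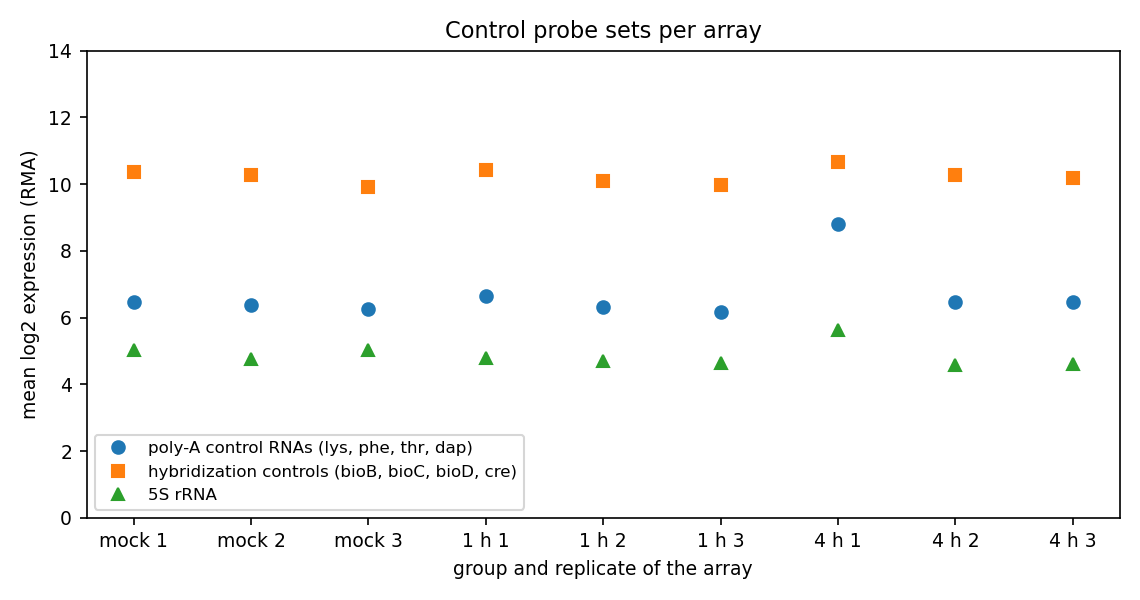
Mean log2 expression of control probe sets on each of the 9 arrays: poly-A control RNAs (circles), hybridization controls (squares) and 5S rRNA (triangles). The poly-A controls of replicate 1 at 4 h lie at 8.80, above the 6.16 to 6.66 of the other 8 arrays.

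The first comparison asked which genes respond within 1 h of PLT2-GR release. Genes of auxin synthesis, transport and conjugation were among them. YUC3 (AT1G04610), an enzyme of auxin synthesis, rose by 2.01 ± 0.20 log2 units (adjusted p = 0.00343), a 4.02-fold rise. The auxin efflux carrier PIN4 (AT2G01420) rose by 1.41 ± 0.11 and the influx carrier LAX2 (AT2G21050) by 0.99 ± 0.13. GH3.3 (AT2G23170), which conjugates auxin to amino acids and is itself auxin-induced, fell by 1.44 ± 0.22 (adjusted p = 0.0292). The other large rises were ADF9 (AT4G34970), an actin-binding protein, at 1.97 ± 0.26, AT3G55550 at 1.72 ± 0.25 from a dim mock level of 3.61, the glucosinolate sulfotransferase SOT17 (AT1G18590) at 1.63 ± 0.18, the cell wall enzyme XTH9 (AT4G03210) at 1.57 ± 0.22 and AT5G14920 at 1.53 ± 0.20. The only other call downward was AT1G17830, at -0.53 ± 0.09.

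The counts given for each list are of its measured members. Of the auxin transport and synthesis genes, 3 of 25 rose at 1 h, 0 fell and 22 did not pass, with 3 up when adjusted over the list alone. As a list they shifted upward (camera adjusted p = 0.00938; adjusted p = 0.584 with an estimated correlation), although their median was 0.01 (-0.07 to 0.045 without single arrays). Without mock replicate 3 this shift had an adjusted p of 0.0543, and without 1 h replicate 2 one of 0.154. Of 22 auxin response genes, GH3.3 fell and 21 did not pass, among them IAA2 at -0.26 and IAA29 at 0.19; 1 was down when adjusted over the list alone, and the list did not shift. RGF peptides and their RGI receptors act on the root meristem upstream of PLT proteins. Of 11 measured, RGI5 (AT1G34110) rose by 0.64 ± 0.08 and 10 did not pass, with RGI1 at 0.68 and RGF8 at 1.48, while 5 were up when adjusted over the list alone. This list shifted upward with the preset correlation (adjusted p = 1.58e-06) and with an estimated one (adjusted p = 0.0303). The 24 ribosome biogenesis genes shifted upward with a median of 0.15; limma called 0 of them and 4 had an unadjusted p under 0.05 (adjusted p = 1.09e-08; adjusted p = 0.267 with an estimated correlation). Values in this list were 0.28 for FIB2, 0.22 for NAP57 and 0.21 for SWA1. The 13 cytokinin response regulators shifted downward with a median of -0.23 (-0.27 to -0.14 without single arrays); limma called 0 of them and 1 had an unadjusted p under 0.05 (adjusted p = 0.0016; adjusted p = 0.518 with an estimated correlation). ARR4 stood at -0.34, ARR5 at -0.38 and ARR6 at -0.23.

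Cell cycle genes, expansins and markers of other root cell types showed no call at 1 h. The G2/M list had a median of 0.05 and the G1/S list one of 0.05, and in each limma called 0 members and 0 had an unadjusted p under 0.05. Medians were 0.03 for D-type cyclins, 0.01 for CDK inhibitors and activators of the anaphase-promoting complex (APC), -0.08 for expansins, 0.02 for stem cell niche regulators and 0.03 for the PLT family. They were -0.08 for root cap, 0.01 for epidermis, -0.10 for endodermis and -0.004 for vascular markers, -0.09 for wound and stress genes, 0.01 for clock genes, -0.04 for embryo and shoot regulators and 0.01 for photosynthesis genes, and without single arrays these medians lay between -0.20 and 0.11. None of these lists shifted, limma called 0 members of each, and between 0 (epidermis, endodermis, clock and photosynthesis) and 5 (niche regulators) members had an unadjusted p under 0.05. The direction of the test or the sign of the mean was opposite to that of the median for the PLT family, root cap, CDK inhibitor, epidermis, vascular, clock and embryo lists. Adjusted over each list alone, the root cap gene FEZ passed at 1.03 and no other member did.

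In all, 40 genes were called at 1 h, of which 38 rose and 2 fell, and 930 had an unadjusted p under 0.05 (499 up, 431 down). Without mock replicates 1, 2 and 3 in turn, 21, 8 and 6 genes were called, without 1 h replicates 1, 2 and 3 the counts were 17, 6 and 6, and without 4 h replicate 1 the count was 61. With only the mock and 1 h arrays fitted, 65 genes were called. YUC3 and PIN4 were the 2 of 11 named calls that passed without any 1 of the 9 arrays, while GH3.3 had an adjusted p of 0.106 to 0.211 without any 1 mock or 1 h array and of 0.0596 without 4 h replicate 2.

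**Figure D2:**
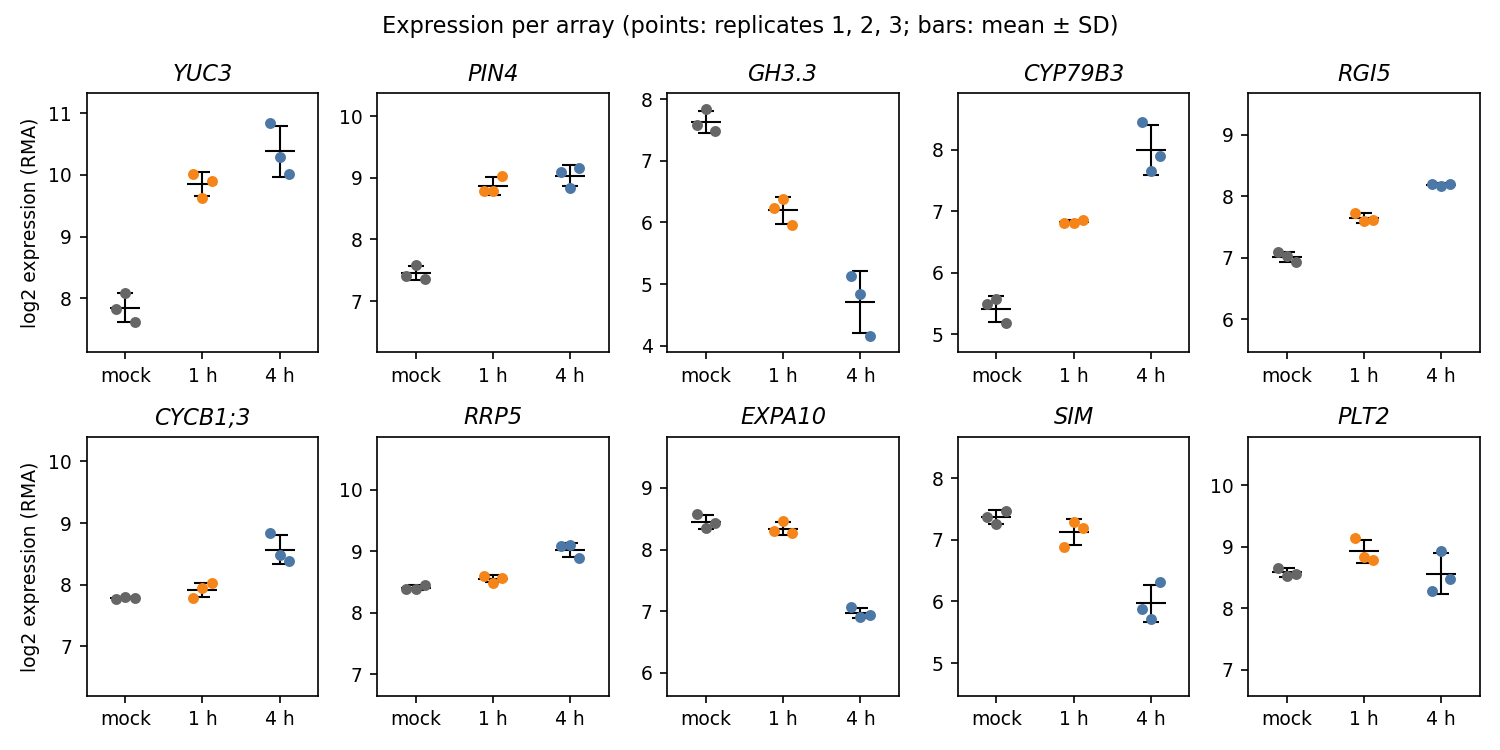
Log2 expression of 10 named genes on each array (points), with mean and SD of the 3 arrays per group (bars); all panels span the same range of log2 units. YUC3 and PIN4 were higher and GH3.3 lower at 1 h than in mock, while EXPA10 and SIM were lower at 4 h.

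The second comparison asked what had changed by 4 h, against mock arrays incubated for 1 h. CYP79B3 (AT2G22330), which turns tryptophan into indole-3-acetaldoxime, rose by 2.59 ± 0.18 log2 units (adjusted p = 5.37e-05), a 6.01-fold rise. YUC3 rose by 2.54 ± 0.20, the malate synthase gene MLS (AT5G03860) by 2.35 ± 0.10, AT5G14920 by 2.31 ± 0.20, AT4G28410 by 2.25 ± 0.12 and the DELLA gene RGL3 (AT5G17490) by 2.23 ± 0.13. The mock level of RGL3, 3.56, lay near the first quartile of the arrays (3.55 to 3.63); signal near background was not measured, so the size of its change, and of others from dim levels, is uncertain. GH3.3 showed the largest fall, -2.93 ± 0.22 (adjusted p = 8.81e-05). It was followed by AT5G26220 at -2.50 ± 0.24, the beta-glucosidase gene BGLU28 (AT2G44460) at -1.91 ± 0.21, AT1G78020 at -1.70 ± 0.26, AT5G06270 at -1.66 ± 0.26 and AT1G57590 at -1.62 ± 0.18.

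Ribosome biogenesis and G2/M genes shifted upward at 4 h with the preset correlation, beside a median of -0.40 over 21 well measured markers of other root cell types. Of 24 ribosome biogenesis genes, 23 rose, 0 fell and 1 did not pass, with 24 up when adjusted over the list alone; RRP5 rose by 0.61 ± 0.08, RID2 by 0.58 ± 0.09 and RH10 by 0.53 ± 0.08. The list shifted upward with the preset correlation (adjusted p = 1.57e-18; adjusted p = 0.103 with an estimated correlation). Without 4 h replicate 1, the array with the high poly-A controls, 19 of the 24 were called. Of 20 G2/M genes, 12 rose, 0 fell and 8 did not pass, with 16 up when adjusted over the list alone. CYCB1;3 rose by 0.78 ± 0.12, the spindle checkpoint gene MAD2 by 0.68 ± 0.12 and the mitotic kinase gene CDKB2;1 by 0.58 ± 0.10 (list adjusted p = 7.35e-09; adjusted p = 0.373 with an estimated correlation). Without 4 h replicate 1, 6 of the 20 were called. Among 11 CDK inhibitors and APC activators, 2 rose (KRP5 by 0.82 ± 0.14 and KRP4 by 0.59 ± 0.14) and 3 fell (SIM at -1.40 ± 0.15, SMR1 at -1.35 ± 0.25 and CCS52A1 at -1.16 ± 0.17), with 3 up and 4 down when adjusted over the list alone. SIM, SMR1 and CCS52A1 are known to promote endoreduplication. Of 8 D-type cyclins, CYCD3;1 fell by 0.68 ± 0.16 and CYCD4;1 by 0.46 ± 0.11, and 6 did not pass, with CYCD6;1 at 0.20. Of 21 G1/S genes, RNR1 rose by 0.50 ± 0.12 and TSO2 by 0.34 ± 0.10 (adjusted p = 0.056 with arrays centred on their medians), the replication licensing gene CDT1A fell by 0.63 ± 0.09, and 18 did not pass. Adjusted over the list alone, the counts for D-type cyclins and G1/S genes were the same. With 4 h replicate 1 left out, 0 G1/S genes were called up and 1 down, 1 D-type cyclin was called down, and 1 CDK inhibitor or APC activator was called up and 3 down. G1/S genes, D-type cyclins and CDK inhibitors did not shift as lists by camera, though fry called CDK inhibitors and APC activators downward (adjusted p = 0.0317). For D-type cyclins the median was 0.02 (-0.01 to 0.06 without single arrays) and the mean -0.07.

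Among signalling genes, 5 of 11 RGF and RGI genes rose, 1 fell and 5 did not pass at 4 h, with 7 up and 1 down when adjusted over the list alone. RGI5 rose by 1.17 ± 0.08, RGI1 by 1.17 ± 0.12, RGF8 by 1.48 ± 0.27, RGF3 by 1.37 ± 0.24 and RGF4 by 0.91 ± 0.21, and RGI4 fell by 1.40 ± 0.18 (list adjusted p = 0.00399 upward; adjusted p = 0.126 with an estimated correlation). Without 4 h replicate 1, 4 were called up and 1 down. Of 25 auxin transport and synthesis genes, 5 rose, 0 fell and 20 did not pass, with 5 up and 6 down when adjusted over the list alone. These were YUC3, YUC7 at 0.73, YUC8 at 0.62, PIN4 at 1.58 ± 0.11 and LAX2 at 1.04 ± 0.13; the list median was -0.16 (-0.18 to -0.01 without single arrays), the mean 0.08, and the list test did not pass. Of 22 auxin response genes, 3 fell, GH3.3, GH3.1 by 0.54 ± 0.13 and IAA2 by 0.40 ± 0.10, and 19 did not pass. Of 13 cytokinin response regulators, ARR10 fell by 0.68 ± 0.17 and ARR1 by 0.58 ± 0.15, and 11 did not pass, with ARR12 at -0.32. Adjusted over each list alone, the counts for auxin response and cytokinin genes were the same. When 4 h replicate 1 was left out, 4 auxin transport and synthesis genes were called up, 2 auxin response genes were called down, and 0 cytokinin regulators passed. The auxin response and cytokinin lists did not shift by camera (adjusted p = 0.0612 and 0.123), although auxin response genes did without 4 h replicate 1 (adjusted p = 0.0242). With all arrays fry called auxin response genes downward (adjusted p = 0.0403).

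Expansins, which loosen cell walls, moved downward as a list at 4 h (adjusted p = 0.000587; adjusted p = 0.276 with an estimated correlation). Of 9, 4 fell: EXPA10 by 1.48 ± 0.09, EXPA17 by 1.13 ± 0.19, EXPA1 by 1.11 ± 0.14 and EXPA8 by 1.07 ± 0.19; 5 did not pass, and the count adjusted over the list alone, and that without 4 h replicate 1, was also 4. Of 11 root cap markers, FEZ, a regulator of root cap stem cell division, rose by 0.97 ± 0.24 and 10 did not pass, while 1 was up and 5 down when adjusted over the list alone. ARF16 stood at -0.30 and ARL2 at -0.28, and the list shifted downward (adjusted p = 0.0266; adjusted p = 0.516 with an estimated correlation). Of 11 endodermis markers, ESB1 fell by 0.52 ± 0.14 and 10 did not pass, with MYB36 at -0.66 and SGN3 at -0.46, and 4 were down when adjusted over the list alone (list adjusted p = 0.0251; adjusted p = 0.506 with an estimated correlation). Without mock replicate 2 the adjusted p was 0.0518 for root cap and 0.0727 for endodermis markers; root cap markers did not pass without 4 h replicate 2 (0.16), endodermis markers did not without 4 h replicate 1 (0.0864), and neither did without the dim probe sets (0.0827). Of 13 epidermis and root hair markers, RHD6 fell by 0.81 ± 0.16 and RHD2 by 0.72 ± 0.20 (adjusted p = 0.0511 after quantile normalization), and 11 did not pass, with MYB23 at -0.40. Of 22 vascular markers, 4 fell, XCP1 by 0.69 ± 0.15, TMO5 by 0.52 ± 0.11, ACL5 by 0.47 ± 0.13 and NAC086 by 0.42 ± 0.11, while PHB rose by 0.64 ± 0.14 and 17 did not pass. Epidermis and vascular markers did not shift as lists, and adjusted over each list alone the counts were the same. Without 4 h replicate 1, limma called 0 root cap and 0 endodermis markers, 1 epidermis marker down, and 1 vascular marker down and 0 up. Over the 21 markers of these 4 other cell types with a mock level of at least 6, the median log2 fold change at 4 h was -0.40 (bootstrap 95% interval over genes -0.49 to -0.16), beside the falls of the expansins. Choosing markers by their level on the mock arrays, which also served as the baseline, favours falls, and it left out FEZ. Over all measured markers the medians were -0.35 for root cap, -0.11 for epidermis, -0.20 for endodermis and -0.16 for vascular genes.

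Of 20 stem cell niche regulators, TMO7 rose by 0.53 ± 0.10, MYB56 rose by 0.70 ± 0.19, UPB1 fell by 0.65 ± 0.16 and 17 did not pass, and the list did not shift. Leaving out 4 h replicate 1, limma called 1 niche regulator up and 0 down. CUC2 rose by 1.47 ± 0.24 among 15 embryo and shoot regulators, with FUS3 at 0.30 and L1L at 0.26, and 14 did not pass. Adjusted over each list alone, the counts of both were the same. The 6 photosynthesis genes shifted upward; limma called 0 of them and 3 had an unadjusted p under 0.05 (list adjusted p = 0.0379; adjusted p = 0.382 with an estimated correlation), with LHCA1 at 0.61, PSBO1 at 0.30 and PSAF at 0.30. This shift did not pass after quantile normalization (adjusted p = 0.0558), without mock replicate 2 (0.0727) or without 4 h replicate 1 (0.167). None of the 8 PLT family genes (median -0.01), 15 wound and stress genes (-0.17) or 12 clock genes (0.26) was called by limma at 4 h, 2 of each list had an unadjusted p under 0.05, and these lists did not shift. Without single arrays these medians ranged from -0.095 to 0.05, from -0.26 to -0.07 and from 0.08, without 4 h replicate 1, to 0.35. The values of KRP4, SMR1, RGF8, RGF3, RGF4, YUC7, YUC8, EXPA8, ACL5 and NAC086 were seen before these genes were chosen to be named. In all, 2305 genes were called at 4 h, of which 1185 rose and 1120 fell, and 5737 had an unadjusted p under 0.05; 171 of those called changed at least 2-fold, and the median absolute log2 fold change of a call was 0.52. Without mock replicates 1, 2 and 3 in turn, 1223, 688 and 896 genes were called, and without 4 h replicates 1, 2 and 3 the counts were 1209, 1189 and 4153. With only the mock and 4 h arrays fitted, 1067 genes were called. Of the 49 calls named by the rule fixed beforehand, 31 passed without any 1 of the 9 arrays, among them GH3.3, YUC3, CYP79B3, PIN4, SIM and EXPA10. The others lost the call without at least 1 array: GH3.1, IAA2, ARR10, ARR1, CYCD3;1, CYCD4;1, RNR1, TSO2 and ESB1. RHD6, RHD2, FEZ, TMO7, UPB1, MYB56, TMO5, XCP1 and PHB lost it too. Of the 10 calls named after their values were seen, 5 passed without any 1 array, SMR1, RGF8, RGF3, YUC7 and EXPA8.

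**Figure D3:**
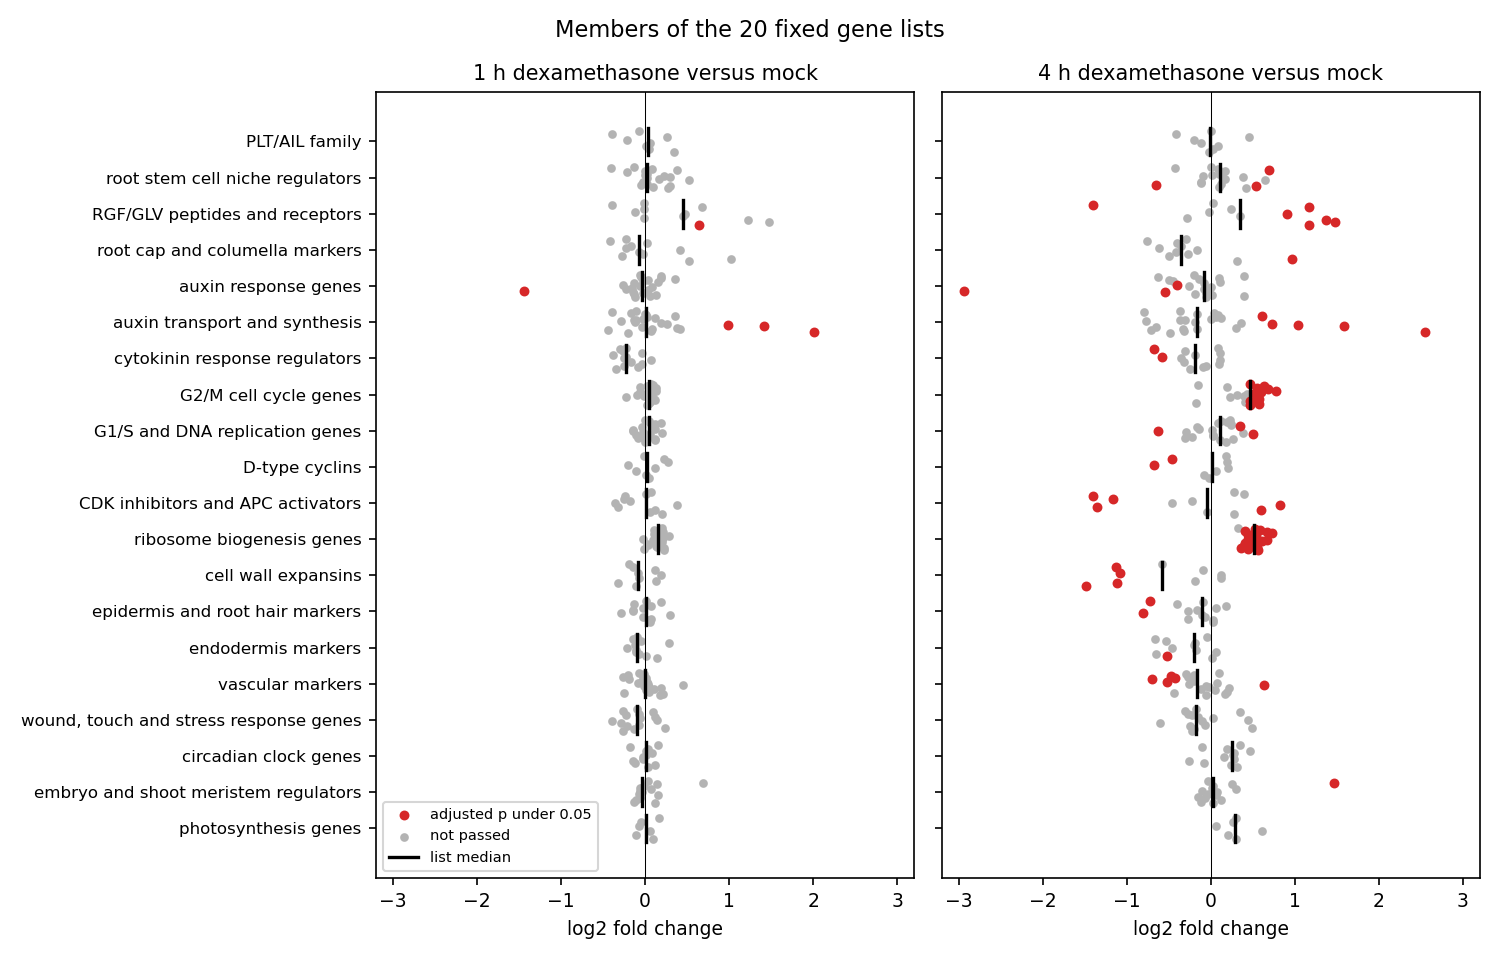
Log2 fold change of each measured member of the 20 lists at 1 h (left) and 4 h (right) against mock; red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. At 4 h, 23 of 24 ribosome biogenesis and 12 of 20 G2/M genes had risen.

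Between 1 h and 4 h, 397 genes were called, of which 190 rose and 207 fell. The 4 largest rises were AT3G48460 at 1.43 ± 0.30, AT3G48450 at 1.25 ± 0.26, MLS at 1.19 ± 0.10 and CYP79B3 at 1.17 ± 0.18. The 4 largest falls were AT5G26220 at -1.88 ± 0.24, AT1G78020 at -1.66 ± 0.26, AT5G62330 at -1.60 ± 0.24 and BGLU28 at -1.52 ± 0.21. PLT1 (0.09 ± 0.09) and PLT2 (-0.36 ± 0.16) were not called. Of the 397 genes, 380 were also called in the same direction at 4 h against mock.

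Ribosome biogenesis, G2/M and expansin genes also shifted between the times with the preset correlation. Of 24 ribosome biogenesis genes, 5 rose (22 adjusted over the list alone), RRP5, RID2, APUM24, NOF1 and SWA2, the last 3 chosen after their values were seen. Of 20 G2/M genes, 6 rose (17 adjusted over the list alone), and the photosynthesis list had 0 calls by limma (2 adjusted over the list alone, 2 at an unadjusted p under 0.05). These lists shifted upward (adjusted p = 8.36e-15, 5.28e-10 and 0.024), and with an estimated correlation the adjusted p was 0.174, 0.312 and 0.420. Expansins shifted downward (adjusted p = 1.25e-05; adjusted p = 0.199 with an estimated correlation), with EXPA10, EXPA17, EXPA1 and EXPA8 called (5 down adjusted over the list alone). Markers of other cell types shifted downward beside them, with an adjusted p of 0.00495 for root cap, 0.024 for vascular, 0.0241 for endodermis and 0.0387 for epidermis. With an estimated correlation the adjusted p was 0.429, 0.301, 0.466 and 0.466. Of these markers limma called TMO5 alone, and adjusted over each list alone 4 vascular, 1 root cap and 1 endodermis marker were down. At an unadjusted p under 0.05, 3 root cap, 4 endodermis and 2 epidermis markers were down.

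The remaining lists did not shift between the times, with an adjusted p of 0.0547 for auxin response genes and 0.0809 for clock genes and higher values for the others. Auxin response genes did shift downward between the times without 4 h replicate 1 (adjusted p = 0.0167, median -0.17). Called members were RGI5 up and RGI4 down (3 up and 1 down adjusted over the list alone), GH3.3 down (1 down), CDT1A down (1 up and 1 down), CYCD4;1 down (1 down) and SIM and CCS52A1 down (3 up and 3 down). Adjusted over the list alone, 1 niche regulator was up and 1 down, and 1 auxin transport or synthesis gene was up and 2 were down. Limma called 0 members of the PLT, cytokinin, wound, clock and embryo lists, also adjusted over the list alone, and 1, 2, 0, 0 and 2 of them had an unadjusted p under 0.05. The wound and stress list had a median of 0.001 (-0.10 to 0.08 without single arrays) with a test in the opposite direction.

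The count of 397 genes between the times was 60, 82 and 19 without mock replicates 1, 2 and 3, 21, 3 and 3 without 1 h replicates 1, 2 and 3, and 30, 30 and 2808 without 4 h replicates 1, 2 and 3. Of 8 calls named by the rule, MLS was the 1 that passed without any 1 array, and of the 17 other calls named here EXPA10 was the only 1. With only the 1 h and 4 h arrays fitted, 4 genes were called. Without 4 h replicate 1, limma called 0 of the ribosome biogenesis and 0 of the G2/M genes between the times, while the lists still shifted (adjusted p = 1.93e-14 and 1.17e-08), with medians of 0.33 (0.36 with all arrays) and 0.33 (0.42). It then called 1 expansin and 1 auxin response gene, both down, and 0 RGF and RGI, G1/S, D-type cyclin, CDK inhibitor and vascular genes. The shifts of photosynthesis, epidermis and endodermis genes did not pass without it (0.142, 0.176 and 0.142). Without 4 h replicate 2, root cap (0.0646), epidermis (0.193) and vascular markers (0.0775) did not pass. Leaving out 1 h replicates ended the shift of photosynthesis genes (replicate 1, 0.0515), of vascular markers (replicate 2, 0.0709), and of epidermis and endodermis markers (replicate 3, 0.0951 and 0.115).

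All 40 genes called at 1 h were also called in the same direction at 4 h (38 up, against 2.1 expected of independent lists, and 2 down, against 0.105). In simulations of unchanged groups against shared mock arrays 0 genes were called at both. Such data gave almost no calls to overlap, with a mean of 0.08 rises and 0 falls at 1 h and 0 rises and 0.08 falls at 4 h. Of the 40, 35 were farther from mock at 4 h than at 1 h, 11 had moved further by the test between the times (10 up, 1 down) and 0 had moved back. Across genes, which are not independent replicates, the fold changes at 1 h and 4 h correlated at 0.591, against 0.500 for unchanged groups with shared controls, and the covariance was 0.0247 against 0.00798, a difference of 0.0167. The 3 mock arrays are too few to be divided between the comparisons, and the counts expected of independent lists leave out their sharing, so part of the excess of calls over these counts may come from the shared controls. Shared controls add the same covariance with or without effects, so the difference in covariance would leave them out if the simulated errors matched the real ones. The simulated errors were independent with the same spread in all groups, while the real median SD was 0.10 in mock and 0.145 at 4 h. The difference may therefore still hold part of the shared controls.

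**Figure D4:**
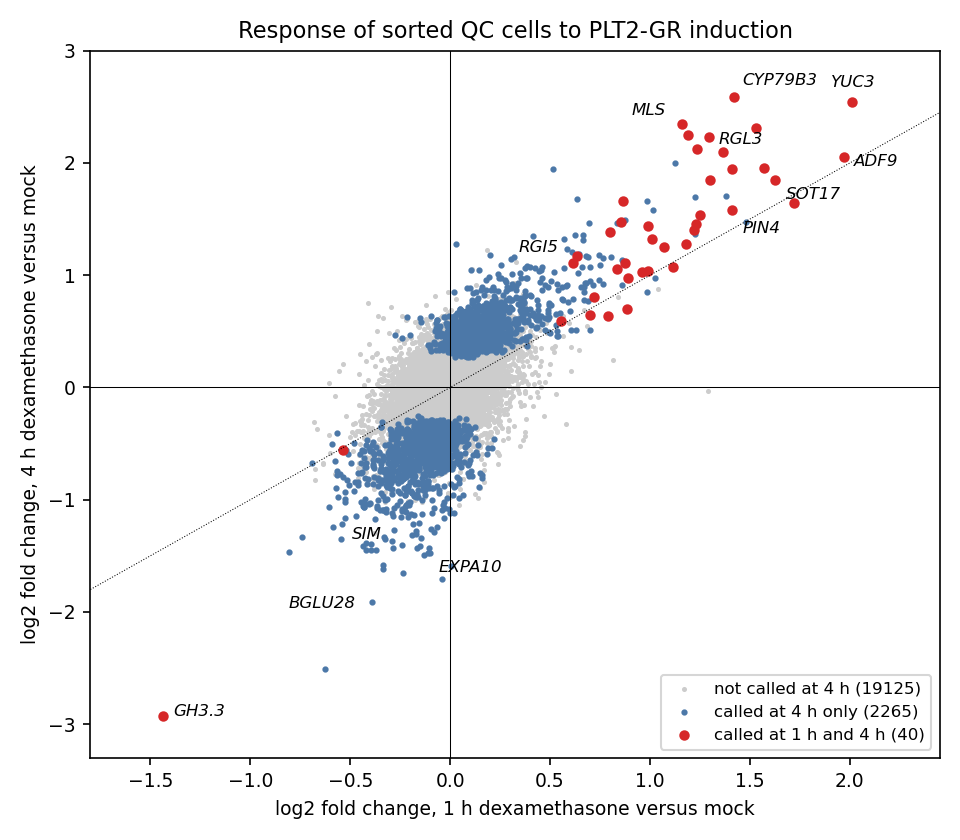
Log2 fold change at 4 h against that at 1 h for 21430 loci; red points were called at both times (40), blue points at 4 h and not at 1 h (2265) and grey points not at 4 h (19125). The dotted line marks equal change, and both axes share the mock arrays.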

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

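Of the tests below, those of incubation time and of the size of the changes lost without 4 h replicate 1 were chosen only after the results they bear on were seen.

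On 4 h replicate 1 the control RNAs added to the samples, which were outside the comparisons, stood above the highest mock array by 2.84 log2 units for lys, 2.27 for phe, 2.20 for thr and 1.99 for dap. This array also had the highest mean of hybridization controls (10.7, others 9.91 to 10.4), the highest 5S rRNA signal (5.63, others up to 5.04) and the largest actin 3' to 5' difference (1.37, others up to 1.25), and it lay farthest out on the first principal component (40.7, with 4 h replicate 3 at 4.25). Its GAPDH 3' to 5' difference (0.04, others -0.08 to 0.15) and 25S rRNA signal (12.8, others 12.5 to 13.0) were ordinary. A candidate explanation is a smaller amount or lower quality of plant RNA in this sample, and the question is how far the calls at 4 h rest on it. Without this array 48.2% of the calls against mock were kept in the same direction, just under the 50% set as the bound, so the part that low input may play cannot be told apart. Leaving out 4 h replicate 2, whose controls were ordinary, also kept 48.2%, and leaving out 4 h replicate 3 kept 95.4%, with 107 calls lost. The calls thus rested on replicates 1 and 2 more than on replicate 3. In the 1195 calls lost without replicate 1, a median of 85.3% of the log2 change was left in the other 2 arrays (95% bootstrap interval over genes 84.5 to 86.1), the lowest of the shares (94.4% for the calls lost without replicate 2 and 91.0% without replicate 3); as a change in 1 array alone would seldom be called with all 3, this excludes nothing and the explanation stays open.

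Between 1 h and 4 h the change differed for 397 genes. Among named genes the log2 change from 1 h to 4 h was -1.88 for AT5G26220, -1.66 for AT1G78020, -1.60 for AT5G62330, -1.52 for BGLU28, -1.49 for GH3.3, -1.42 for AT5G06270 and -1.28 for AT1G57590. It was -1.37 for EXPA10, -0.99 for EXPA17, -0.79 for EXPA1, -1.16 for SIM, -0.91 for CCS52A1, -1.0 for RGI4, -0.68 for CYCD4;1, -0.54 for TMO5 and -0.48 for CDT1A. On the rising side it was 1.43 for AT3G48460, 1.25 for AT3G48450, 1.19 for MLS, 1.17 for CYP79B3, 1.06 for AT4G28410, 0.93 for RGL3, 0.65 for CYCB1;3, 0.63 for MAD2, 0.54 for RGI5, 0.48 for RID2, 0.47 for RRP5 and 0.47 for CDKB2;1. Median log2 changes of the lists that shifted with the preset correlation were 0.42 for G2/M, 0.36 for ribosome biogenesis and 0.26 for photosynthesis genes. They were -0.38 for expansins, -0.25 for root cap, -0.24 for endodermis, -0.13 for epidermis and -0.12 for vascular genes. With an estimated correlation 0 lists shifted between the times. The medians that moved by over 1.5 times on leaving out single arrays ranged from 0.17 to 0.32 for photosynthesis, -0.72 to -0.30 for expansins, -0.42 to -0.13 for root cap, -0.30 to -0.07 for epidermis and -0.17 to -0.03 for vascular genes.

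Calls at 4 h may also come from a longer incubation than the mock arrays, by 3 h, and falls at 4 h from a lower share of other root cell types among the cells sorted by GFP. The 40 genes called at 1 h differed from mock at equal incubation, which argues against incubation as the whole cause for them. They were also called in the same direction at 4 h, which adds little because both comparisons used the same mock arrays. For the further change of these genes by 4 h, incubation and release of PLT2-GR cannot be told apart. For the 2265 genes called at 4 h alone, incubation and release of PLT2-GR cannot be told apart, because no array was a 4 h mock. Limma called 0 clock genes at 4 h (2 at an unadjusted p under 0.05), which does not settle it. For the calls against mock at both times, an effect of dexamethasone itself cannot be told apart from release of PLT2-GR either. No array came from dexamethasone-treated plants without the construct. The 21 well measured markers of other cell types, led by RCPG with a mock level of 11.6 and a log2 change of -0.41, had a median of -0.402 (95% bootstrap interval over genes -0.493 to -0.163), with -0.405 for 8 root cap, -0.403 for 5 epidermis, -0.201 for 7 vascular markers and -0.65 for the 1 endodermis marker. This lies above the median of the called falls, -0.536, the bound set beforehand, but the bound was badly chosen. The markers were lower too, with a median of -0.478 to -0.276 without single arrays, and called falls lie on both sides of their median. The interval is over genes, so it does not measure the spread between arrays. The 21 markers were chosen by their level on the mock arrays, which also served as the baseline, and this favours falls. Over all measured markers the medians at 4 h were -0.35 for root cap, -0.11 for epidermis, -0.20 for endodermis and -0.16 for vascular genes. Cell share and regulation thus cannot be told apart, and for the rises, which a higher share of QC cells could also bring, this was not tested.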

How the results depend on the processing

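The settings here were planned; only the counts of list members without 4 h replicate 1, and the list medians and the genes named outside the rule without single arrays, were added after the data were examined. Testing all probe sets separately was not run, as each locus had 1. Quantile normalization, centring on medians, and trend with robust eBayes left the 3 counts of genes within 1.5 times of those reported, as did leaving out dim probe sets. Array weights gave 79 genes at 1 h, 1699 between the times and 76 called at both times; the weight was 0.381 for 4 h replicate 1 and 0.516 for 4 h replicate 3. Fits of only the groups compared gave 65, 1067 and 4 genes; the 397 calls between times thus draw on the spread estimated with the mock arrays. A minimum absolute log2 fold change of 1 gave 23, 171 and 36 genes, and 23 at both times, by its own construction. Leaving out each array gave 6 to 61 genes at 1 h, 688 to 4153 at 4 h, 3 to 2808 between the times and 6 to 60 at both times, the highest 4 h counts without 4 h replicate 3. Fewer arrays leave fewer degrees of freedom, which alone would lower a count. On the first principal component 4 h replicate 3 lay at 4.25, apart from 4 h replicates 1 and 2 at 40.7 and 27.3. The cause of the higher counts was not tested. Shifted lists ranged from 4 to 12 at 4 h (4 without mock replicate 2, 12 without mock replicate 1) and from 5 to 9 between the times. Without dim probe sets 4 lists shifted at 4 h and 4 between the times. With an estimated correlation 1, 0 and 0 lists shifted, the RGF and RGI list at 1 h. Camera with the preset value had called 4, 7 and 8, and fry called 1 at 1 h, 6 at 4 h and 3 between the times. At 4 h fry called auxin response genes and CDK inhibitors and APC activators, which camera did not. Fry did not call root cap and endodermis markers (adjusted p = 0.144 for both) or photosynthesis genes (0.0544), which camera did.

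Pairing of the arrays by replicate number was not clear: 2 of 9 pairs with the same number had correlated deviations above 0.1 (-0.131 to 0.273), and 5 of 9 arrays correlated best with their own number. Pairs with different numbers went further, to 0.427 for 1 h replicate 1 with 4 h replicate 2. For 1 h replicate 1 with 4 h replicate 3 the value was -0.459. What these arrays shared was not tested. With the replicate block as a fixed factor 36, 2340 and 422 genes were called, and as a random effect 40, 2298 and 385. Of 1621 values of named genes under alternatives, 1393 kept direction and call, 201 lost the call, 19 gained it and 8 uncalled values changed sign. These were PLT1 at 1 h (-0.005 centred on medians; -0.041 to 0.044 without single arrays) and PLT2 at 4 h (0.137 with array weights; -0.205 to 0.122 without single arrays), all near 0; the cause was not tested. Signal near background was not measured, so values of dim genes such as PLT1 are less certain.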

Other observations

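The lists of indole glucosinolate, tryptophan, aliphatic glucosinolate, jasmonate and gibberellin genes were chosen after the data were examined, so their p-values are not independent evidence, and the test of dexamethasone itself was chosen after the result was seen.

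Genes of indole glucosinolate synthesis, which share the precursor indole-3-acetaldoxime with one route to auxin, rose at both times. Of 16, 6 rose at 1 h: CYP79B3 by 1.42 ± 0.18 log2 units, APK2 by 1.41 ± 0.16, CYP83B1 by 1.37 ± 0.20, CYP79B2 by 1.23 ± 0.14, SOT16 by 1.22 ± 0.17 and UGT74B1 by 0.84 ± 0.13 (10 up adjusted over the list alone; camera adjusted p = 2.49e-22; adjusted p = 0.00766 with an estimated correlation). At 4 h 10 rose (11 adjusted over the list alone), with CYP79B2 at 2.12 and SUR1 at 1.14 (adjusted p = 1.46e-11; adjusted p = 0.0392 with an estimated correlation), and the count was 10 without 4 h replicate 1. The regulators MYB34 (0.84 at 1 h), MYB51 (-0.05) and MYB122 (0.05) were not called. Of 8 tryptophan synthesis genes listed 4 were measured, and these 4 rose at 4 h, ASA1 by 0.73, PAT1 by 0.69, IGPS by 0.67 and TSA1 by 0.66 (adjusted p = 1.56e-05; adjusted p = 0.0392 with an estimated correlation). At 1 h limma called 0 of them, 2 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone (camera adjusted p = 1.81e-06; adjusted p = 0.0265 with an estimated correlation).

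Among 19 gibberellin metabolism and DELLA genes, RGL3 rose by 1.29 ± 0.13 at 1 h from a dim mock level of 3.56 (list adjusted p = 0.00133; adjusted p = 0.144 with an estimated correlation). At 4 h 5 rose, RGL3, the early biosynthesis gene GA3 by 1.49, KAO2 by 1.05, RGL1 by 0.78 and RGL2 by 0.43, while GA3OX1 fell by 0.77 and GA3OX2, enzymes of the final step, fell by 0.62 (list adjusted p = 0.142). Of 10 aliphatic glucosinolate genes SOT17 alone was called, at both times (list adjusted p = 0.0777 at 1 h and 0.0478 at 4 h; adjusted p = 0.144 and 0.104 with an estimated correlation). At 4 h, 2 aliphatic glucosinolate genes were called up without replicate 1 (list adjusted p = 0.00724), and 4 gibberellin genes up and 3 down. The 11 jasmonate genes had 0 calls by limma at both times, 1 and 0 at an unadjusted p under 0.05, and shifted downward at 1 h (list adjusted p = 0.00371; adjusted p = 0.149 with an estimated correlation) and not at 4 h (adjusted p = 0.674).

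A wound or jasmonate response to root cutting and protoplasting is a candidate explanation for the rise of indole glucosinolate genes at 1 h, besides release of PLT2-GR. Mock and 1 h samples both went through these steps after equal incubation, so only a response that differed between them could give the rise. The median of the jasmonate list at 1 h was -0.15 (95% bootstrap interval over genes -0.174 to -0.086). This is below the 0.4 that is 50% of the indole list's median, which argues against a jasmonate response as the whole cause. The bound was taken from a list chosen after the data were examined, and the interval over genes does not measure the spread between arrays. An effect of dexamethasone itself cannot be told apart, since 0 arrays came from treated plants without the construct.

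At 1 h 38 of the 40 calls were rises. This share moved by at most 0.2 percentage points under quantile normalization and centring on medians. The bound of 10 set for it was no test of scaling between arrays, because the array medians already lay between 5.73 and 5.78 and left these settings little to move. In simulated data the recovery of rises minus that of falls of 1 log2 unit was -0.3 percentage points (98.2% against 98.5%), which excludes nothing about the real falls.

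With 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. Fitted with only the groups compared, 1 of the 10 splits, the real one, gave as many calls each time, with 65 genes at 1 h, 1067 at 4 h and 4 between the times, and the highest of the other splits gave 0. The other splits mix arrays of both real groups, so a real difference would itself widen their spread and lower their counts. Their 0 calls are therefore no measure of what unchanged groups would give.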
